A study of Mus musculus with 8 samples.

How the data were processed

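RNA from 8 mouse samples was compared, 4 from wild-type mice and 4 from littermates homozygous for a gene-trap allele of Scn2a, bred from heterozygous pairs. Per the labels, total RNA was isolated with a column kit and made into stranded, paired-end TruSeq libraries. The authors deposited whole-number read counts per Ensembl gene, without normalization, for 54446 genes. Per the submitters' processing notes, FastQC 0.11.3, STAR, featureCounts and edgeR were used with the genome build GRCm38; the versions of the last 3 tools, the annotation release and the strand setting are not given in the sources used here. Total counts per library lay between 27993412 and 37538988.

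Gene names, biotypes and positions came from GENCODE mouse release M21 on GRCm38, which held 54409 of the 54446 gene identifiers; the other 37 carried 0.0143% of the counts. Of 1263 protein-coding genes nested inside another gene on either strand, 1258 stood at 0 in every library, against 13.5% of the 20655 protein-coding genes not nested. So did 669 of the 672 nested ones whose exons are clear of other genes' exons. Counting over exons alone would not give this, whereas counting over whole gene bodies with shared reads dropped would, so the values are taken to include reads of introns, above all for long genes. Of 811 protein-coding genes nested in a gene on the opposite strand, 807 stood at 0, which counting by strand would not give. The counts are thus taken to ignore strand, although the libraries were stranded. Nested genes such as Gfap, Scn2b and Xist therefore have no measured value here, and genes that overlap others are uncertain, with the fraction of the span shared given where it is large.

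Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest, robust option off), with TMM scaling. The filter was filterByExpr at its defaults: about 10 counts in at least 4 libraries, the size of a group, and 15 counts in all. Benjamini-Hochberg adjustment covered all 17395 genes tested, with a threshold of 0.05. The common dispersion was 0.0138, a biological coefficient of variation of 0.117. Levels are CPM, counts scaled to TMM-adjusted library sizes, and log2 CPM used a prior count of 2. Single values were compared by exact two-sided permutation tests over the 70 relabellings, whose smallest p is 0.0286. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 7.09, so each library counted as 1 sample.

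Named genes were chosen by a rule fixed before the data were examined: Scn2a, then the 12 higher and 12 lower protein-coding genes of largest log2 fold change among those past the threshold, with a mean of at least 1 CPM and no overlap between genotypes, then up to 4 members of smallest p from each list. Members of lists may be named beyond that to give a value. A few list members that the rule selects are counted in their lists and not reported here by name. A total of 39 lists, also fixed before the data were examined, covered ion channels, pumps, the axon initial segment, receptors, synaptic vesicles, immediate early genes, neuropeptides, circadian genes, stress and immune genes, mitochondrial and ribosomal genes, and markers of cell types and brain regions. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; 22 passed, 18 lower and 4 higher. With an estimated correlation 1 passed, the immediate early genes. Regroupings of the 8 libraries into 4 and 4 that mix the genotypes called 7 to 22 lists at the preset correlation. The p-values at that setting therefore cannot be taken at face value here. The rotation test fry, which asks whether a list moves 1 way on balance, called 10, and 27 when change in either direction counted. Calls within 5 Mb of Scn2a were compared with other genes by Fisher's exact test.

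Alternatives were DESeq2 1.42.0, limma-voom, robust quasi-likelihood, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 4 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, removal of genes on chromosomes X and Y, a log2 fold change of at least 1, windows of 2 and 20 Mb, and leaving out each library. Chosen after the data were seen were the removal of WT replicate 4 together with HOM replicate 4, a covariate of mean choroid plexus marker level, and the removal of smooth trends with gene span, exonic length and GC content, fitted with mgcv 1.9.3. The median log2 fold change of all genes was 0.00 with TMM, 0.00 with RLE, 0.03 with upper-quartile scaling and 0.07 with library totals only. TMM and RLE aim at a median near 0, so their values do not test for a shared shift. TMM factors differed with genotype, at 0.977 ± 0.0123 in WT and 1.023 ± 0.00546 in HOM (SD, n = 4, exact two-sided permutation test, p = 0.0286).

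The test was tried on simulated data, with counts drawn for the 17395 genes from the means and library sizes of these samples and 200 genes changed. Of 50 genes at each size, 12% were recovered at 1.25-fold, 62% at 1.5-fold, 90% at 2-fold and 90% at 3-fold. Of 137 genes called, 10 were unchanged ones. With so few changed genes, changes below 1.5-fold were thus often missed at this depth and number of samples. In the samples themselves 940 genes were called, which loosens the cut-off after adjustment, so these rates need not carry over.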

Results

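RNA-seq counts were compared between 4 wild-type mouse samples (WT replicates 1 to 4) and 4 samples from littermates homozygous for a gene-trap allele of Scn2a (HOM replicates 1 to 4). Scn2a encodes NaV1.2, a voltage-gated sodium channel of brain neurons, and a gene trap is an inserted cassette that interrupts the transcript of its host gene. The comparison asks how a severe shortage of NaV1.2 alters gene expression in the adult mouse. The labels call the source of the RNA neuron and no brain region is assumed here. They number the samples without saying that each came from a separate mouse, so p-values measure the spread between these samples. Total counts were 37538988, 31174828, 29053382 and 31932312 in WT replicates 1 to 4. They were 35339890, 27993412, 31322949 and 34665959 in HOM replicates 1 to 4, a difference not larger than the spread between replicates (exact two-sided permutation test, p = 1). Transcripts of glia were abundant beside those of neurons: in WT the myelin gene Mbp stood at 2141 ± 408 CPM (counts scaled to library size) and the astrocyte glutamate transporter gene Slc1a2 at 3319 ± 147 CPM. The neuronal kinase gene Camk2a stood at 3862 ± 138 CPM (SD, n = 4 for each). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together held 2 counts in HOM replicate 4 and between 4452 and 5984 counts in each of the other libraries. Sex is not given in the labels, and on these counts it may not be balanced between the genotypes. Long intergenic noncoding RNA genes took 1.31% ± 0.0618 of the counts in WT and 1.57% ± 0.0814 in HOM (SD, n = 4; exact two-sided permutation test, p = 0.0286, the smallest value that 70 relabellings allow).

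Scn2a, the trapped gene, was reduced in every HOM library. Its level was 477, 371, 477 and 415 CPM in WT replicates 1 to 4 and 122, 147, 131 and 112 CPM in HOM replicates 1 to 4, with means of 435 ± 51.6 and 128 ± 15.1 CPM (SD, n = 4). HOM samples thus held 29.4% of the WT level. The log2 fold change was -1.77 (SE 0.10, edgeR quasi-likelihood test, adjusted p = 1.16e-05), and the exact two-sided permutation test of its log2 CPM gave p = 0.0286, again the smallest value the design allows. Scn2a (ENSMUSG00000075318) lies on the plus strand of chromosome 2 in GRCm38, from 65620771 to 65767447, and no other annotated gene overlaps its span. One count per gene cannot separate transcript before the trap from transcript after it, nor reads of exons from reads of introns.

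**Figure D1:**
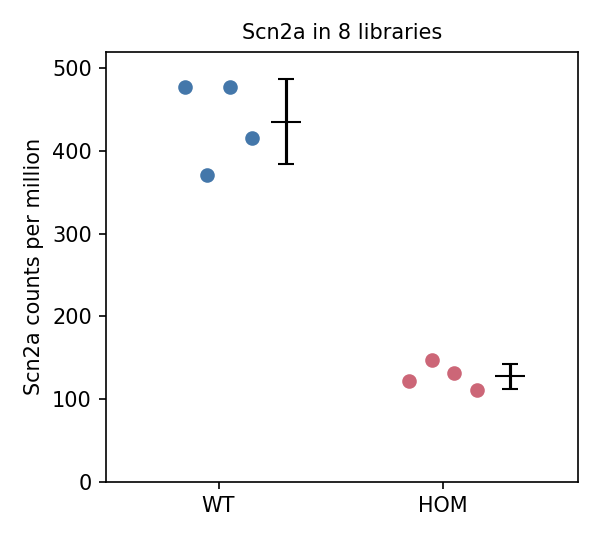
Scn2a level in CPM (vertical axis, from 0) in the 4 WT and 4 HOM libraries; each point is a library, and the bar beside each group gives the mean and SD. The HOM libraries lie between 112 and 147 CPM and the WT libraries between 371 and 477 CPM.

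The lower genes with the largest fold changes were led by transcription factors and signalling genes that neuronal activity induces. Egr2, a zinc-finger transcription factor, fell from 15.3 ± 3.47 CPM in WT to 2.30 ± 0.35 CPM in HOM (SD, n = 4; log2 fold change -2.73, SE 0.18, edgeR adjusted p = 2.30e-05). The AP-1 gene Fos fell from 39.4 ± 8.94 to 10.7 ± 6.88 CPM, its relative Fosb from 23.5 ± 2.23 to 9.15 ± 0.598 CPM. Egr1 fell from 375 ± 38.9 to 129 ± 25.03 CPM and Arc, which encodes a dendritic protein of synaptic plasticity, from 224 ± 45.9 to 80.7 ± 34.3 CPM. Egr4 (log2 fold change -1.37), the MAP kinase phosphatase gene Dusp6 (-1.09) and the prostaglandin synthase gene Ptgs2 (-1.26) fell as well. The remaining lower genes were Steap1 (-1.76), the lysophospholipase D gene Enpp2 (-1.61), Samd3 (-1.14) and the nicotinic receptor subunit gene Chrnb3 (-1.13). Enpp2 spread widely among WT libraries, at 565 ± 406 CPM with 1162 CPM in WT replicate 4, the library richest in choroid plexus transcripts, against 185 ± 36.3 CPM in HOM. Its log2 fold change was -0.98 without WT replicate 4 and -0.18 with the choroid plexus level as a covariate (edgeR adjusted p = 0.837), and adjusted p was 0.0715, 0.0973 and 0.0630 without HOM replicates 1, 3 and 4, 0.118 with robust quasi-likelihood and 0.0615 with the replicate block. Steap1 belongs to the choroid plexus markers described further on. With each library left out in turn Egr2, Fosb, Egr1, Arc, Egr4, Dusp6, Ptgs2 and Samd3 stayed past the threshold. The Fos call was lost without WT replicate 3 (0.0521), without HOM replicate 3 (0.0532), with robust quasi-likelihood (0.0702) and with the covariate (0.191). Steap1 was lost without WT replicate 1 or 4 or any 1 HOM library, Chrnb3 without WT replicate 1, 3 or 4 or HOM replicate 1, 3 or 4, both with the replicate block, and Steap1 with limma-voom as well. The covariate left 5 of the 12 past the threshold, namely Egr2, Fosb, Egr1, Egr4 and Dusp6.

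The 12 higher genes with the largest fold changes were mostly expressed at a few CPM. Dio3, which encodes the deiodinase that inactivates thyroid hormone, rose from 2.15 ± 0.455 to 6.54 ± 2.22 CPM (SD, n = 4; log2 fold change 1.61, SE 0.25, edgeR adjusted p = 0.00692). The neurotensin receptor gene Ntsr1 rose from 15.1 ± 0.977 to 27.2 ± 2.63 CPM and the neurotrophin-3 gene Ntf3 from 3.70 ± 0.643 to 6.60 ± 1.16 CPM. Tsks (1.04), Catsperg1 (0.94), 4930444P10Rik (0.92), Ppp1r42 (0.91), the cation channel gene Trpm1 (0.90), the calsequestrin gene Casq1 (0.89), Prss52 (0.88), the amino acid transporter gene Slc38a4 (0.87) and 4930578G10Rik (0.86, the fraction of its span shared with other genes being 0.62) made up the rest, given as log2 fold changes. Several of these had means below 3 CPM in both groups, so their values rest on few counts. Dio3, Ntsr1, Catsperg1 and 4930578G10Rik stayed past the threshold with each library left out in turn. Calls were lost without WT replicate 3 or HOM replicate 3 for 4930444P10Rik, without either of these or HOM replicate 1 for Ntf3 and Casq1, and without WT replicate 1, 3 or 4 or HOM replicate 1 or 3 for Tsks. Prss52 was lost without any 1 WT library, HOM replicate 1 or HOM replicate 3, Ppp1r42 and Trpm1 in every removal except that of HOM replicate 2, and Slc38a4 in all 8 removals (adjusted p from 0.0516 to 0.102). The replicate block ended the calls of Tsks, Ppp1r42, Trpm1, Prss52 and Slc38a4, limma-voom and 1 surrogate variable that of Ppp1r42, and with the choroid plexus covariate only Ntsr1 and Ntf3 passed.

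In all, 940 of 17395 genes tested differed between genotypes, 429 higher and 511 lower in HOM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: 704 of the 940 were below 1.5-fold, and 15 higher and 40 lower genes reached 2-fold. The CPM values of the genotypes did not overlap at 896 of the changed genes and at 2454 genes, or 14.1% of those tested. Chance gives 2.86% on average over all groupings. Genes vary together, so a single grouping can lie far from that average. Protein-coding genes made up 351 of the higher and 495 of the lower genes, and the longest eighth of protein-coding genes by span held 92 of these higher and 60 of the lower ones, or 162 higher and 228 lower ones after trends of gene span, exonic length and GC content were removed. With upper-quartile scaling the calls were 539 higher and 355 lower. The total was 1873 with DESeq2, 2338 with 1 surrogate variable, 2270 with these trends removed. It was 364 with a replicate block and 38 with the choroid plexus level as a covariate. That level, a mean log2 CPM, stood at 2.52 ± 1.28 in WT and 0.224 ± 0.948 in HOM (SD, n = 4). The covariate thus shares part of its spread with genotype, which weakens the test of genotype. Calls lost under it therefore do not show that choroid plexus content explains them. The count also depended on single libraries, at 527, 957, 181 and 482 genes without WT replicates 1 to 4 and 212, 1187, 180 and 552 genes without HOM replicates 1 to 4, each left out alone, and 335 without WT replicate 4 and HOM replicate 4 together.

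Immediate early genes, which neuronal activity induces within minutes, were lower in HOM as a group. Of 28 measured, 20 fell, none rose and 8 did not pass, with a median log2 fold change of -0.77 (camera, adjusted p = 5.91e-47 with the preset correlation; adjusted p = 0.0399 with an estimated correlation). Adjusted over the list alone, 24 were lower and 1, Jun, was higher. The falls covered the Egr family, with Egr3 going from 174 to 99.2 CPM (log2 fold change -0.81, SE 0.07), and the orphan nuclear receptors Nr4a1 (from 157 to 78.7 CPM), Nr4a2 (log2 fold change -0.30) and Nr4a3 (-1.04). Genes of slower induction were included: the neurotrophin gene Bdnf (-0.70) and the synaptic scaffold gene Homer1 (-0.65) fell, whereas Scg2 (-0.07, SE 0.09) and Vgf (-0.35, SE 0.12) did not pass. The number of lower members was 12 without WT replicate 3, 10 without HOM replicate 3 and 7 with the choroid plexus covariate, at a median of -0.80 (camera adjusted p = 4.91e-33). Of the genes named here, Nr4a1 did not pass without WT replicate 1 or 3 or HOM replicate 3 or 4, Nr4a2 without WT replicate 3 or 4 or HOM replicate 1, 3 or 4, and Bdnf and Homer1 without HOM replicate 3.

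**Figure D2:**
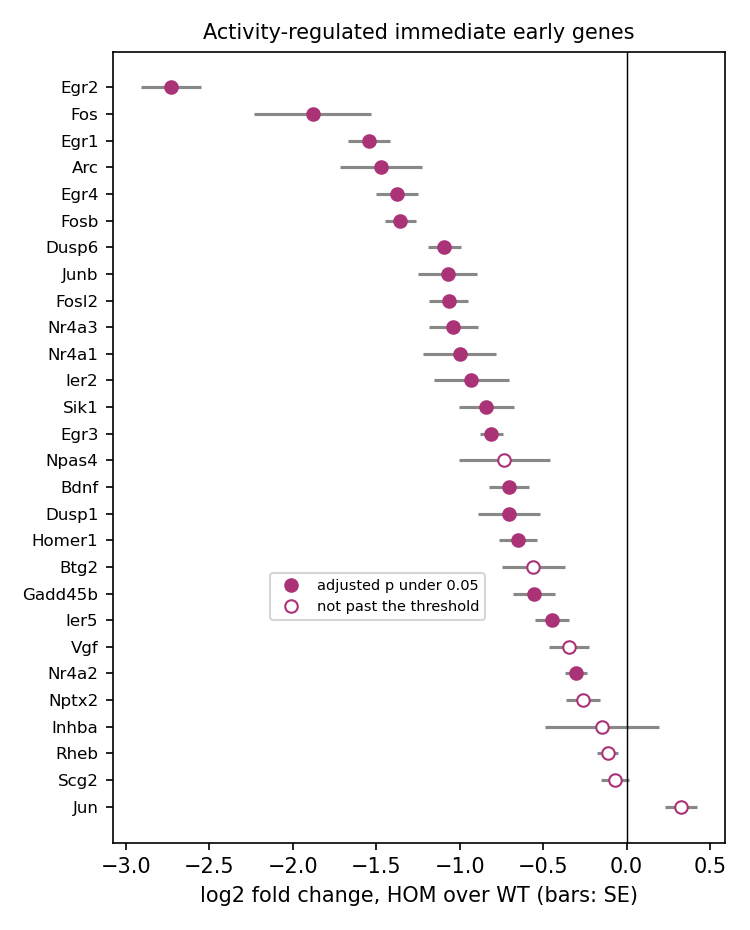
Log2 fold change of HOM over WT (horizontal axis) for the 28 activity-regulated genes, with bars of 1 SE; filled points passed the edgeR test at adjusted p under 0.05 and open points did not. Egr2 lies farthest from 0 at -2.73, and Jun is the member with a positive value.

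Of 15 circadian genes measured, 4 fell in HOM, none rose and 11 did not pass (median -0.17; camera adjusted p = 4.11e-05; adjusted p = 0.253 with an estimated correlation). The repressor gene Bhlhe40 fell from 148 ± 12.2 to 92.8 ± 10.2 CPM, Per1 by 0.51, Per2 by 0.54 and Cry1 by 0.43 on the log2 scale. Adjusted over the list alone, 6 were lower and 1 was higher. The output gene Dbp (log2 fold change -0.17, SE 0.15) and the core activator gene Arntl (0.27, SE 0.08, edgeR adjusted p = 0.055) did not pass. With the choroid plexus covariate 2 circadian genes were lower, at a list median of -0.24 (camera adjusted p = 1.39e-07). Cry1 did not pass without WT replicate 3 or 4 or HOM replicate 1 or 3.

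Voltage-gated potassium channel genes were lower in HOM on balance. Of 36 measured, 5 fell and none rose: Kcnv1, a modulatory subunit, from 103 to 66.6 CPM, Kcna2 from 334 ± 30.0 to 233 ± 31.6 CPM, Kcna1 from 85.6 to 57.0 CPM, Kcng4 (log2 fold change -0.76) and Kcnf1 (-0.26). The median over the list was -0.19 (camera adjusted p = 2.05e-04; adjusted p = 0.253 with an estimated correlation), and 12 were lower and 1 higher when adjusted over the list alone. Published work on these mice is known to have followed this family, so its direction is not independent evidence. With 1 library left out, lower members numbered 3, 5, 2 and 4 without WT replicates 1 to 4. They numbered 1, 6, 1 and 3 without HOM replicates 1 to 4, and 1 member was higher without WT replicate 2. Kcnv1 passed in all 8 removals and Kcnf1 in none. With the choroid plexus covariate no member passed, at a median of -0.21 (camera adjusted p = 0.00118). Among 33 other potassium channels the sodium-activated channel gene Kcnt1 rose (0.31, SE 0.07), whereas the leak channel gene Kcnk1 (-0.32) and the glial inward rectifier gene Kcnj10 (-0.43) fell. That list did not pass (camera adjusted p = 0.0633), and none of its members passed without WT replicate 1, 3 or 4 or HOM replicate 1, 3 or 4. The list passed without WT replicate 4 (0.0140), without HOM replicate 1 (0.0465), without WT replicate 4 and HOM replicate 4 together (0.0239), with the covariate (0.0227, median -0.15 against -0.11) and with span, length and GC trends removed (0.0199, median -0.17). None of 11 auxiliary subunit genes passed; their median was 0.05 and their mean -0.19 (camera adjusted p = 0.889), and Kcne2, also a choroid plexus marker, had the smallest p (-2.45, SE 0.70, edgeR adjusted p = 0.0617). Adjusted over the list alone, 1 of the other potassium channels was higher and 3 were lower, and 1 auxiliary subunit gene was lower.

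Among 12 sodium channel genes other than Scn2a, the gene Scn1a fell from 202 ± 26.5 to 139 ± 28.9 CPM (log2 fold change -0.54, SE 0.14, edgeR adjusted p = 0.0439) and 11 did not pass, including Scn8a (-0.17, SE 0.08) and Scn4b (-0.42, SE 0.14). The Scn1a call was lost without WT replicate 1, 3 or 4 or HOM replicate 1, 3 or 4, each left out alone (adjusted p from 0.0655 to 0.137). It was also lost with upper-quartile scaling (0.0520), a filter of 1 CPM (0.0513), the replicate block (0.0543), WT and HOM replicates 4 left out together (0.0657) and the choroid plexus covariate (0.226), at log2 fold changes from -0.66 to -0.40 over these settings. The list as a whole did not pass (camera adjusted p = 0.0598) but did without WT replicate 2 (0.0458), HOM replicate 2 (0.0418) or HOM replicate 3 (0.0296), with the replicate block (0.0409) and with span, length and GC trends removed (0.0449), and adjusted over the list alone 1 was lower. Of 13 sodium pumps and exchangers 3 fell, among them the sodium pump gene Atp1b1 (-0.30) and the exchanger gene Slc24a3 (-0.29). The median was -0.18 (camera adjusted p = 0.0308; adjusted p = 0.322 with an estimated correlation), with 7 lower when adjusted over the list alone. The camera adjusted p of this list was 0.0870 without WT replicate 1, 0.0602 without WT replicate 3, 0.0641 without HOM replicate 4 and 0.0749 with the replicate block. Its mean log2 CPM did not separate the genotypes (exact two-sided permutation test, p = 0.171). Its lower members numbered 1 without WT replicate 3, HOM replicate 1 or HOM replicate 3, 5 without HOM replicate 2 and 1 with the covariate, at a median of -0.19. Among 26 genes of the calcium channel list the pore-forming subunit genes Cacna1c (0.42), Cacna1d (0.33) and the T-type Cacna1g (0.29) rose (camera adjusted p = 0.189). The 1 lower member was Cacng3 (-0.31), a gene of the gamma subunit family and not a pore-forming one. No member of this list passed without WT replicate 3, HOM replicate 1 or HOM replicate 3 or with the covariate (median 0.04 against 0.05). Without WT replicate 4, 0 were higher, and without WT replicate 1, 2 were higher and 0 lower. Of 17 HCN, chloride channel and cotransporter genes, Clcn1 rose (0.57, SE 0.10), and Slc12a2 (-0.49, SE 0.14) was among 16 that did not pass (camera adjusted p = 0.0972). When adjusted over the list alone, 4 calcium channel genes were higher and 1 was lower, and of the HCN and chloride list 1 was higher and 7 were lower.

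**Figure D3:**
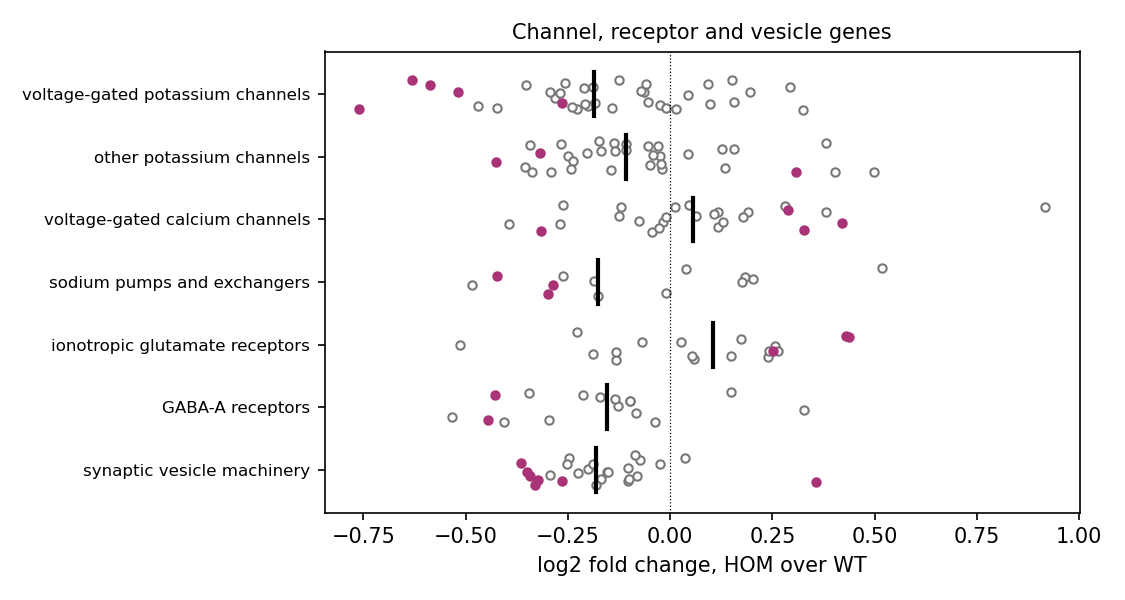
Log2 fold change of HOM over WT (horizontal axis) for members of 7 gene lists; each point is a gene, filled where the edgeR test passed at adjusted p under 0.05, and the thick black line marks the list median. The median is -0.19 for voltage-gated potassium channels and 0.10 for ionotropic glutamate receptors.

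Genes of synaptic vesicles were lower in HOM on balance, whereas 3 of 18 ionotropic glutamate receptor genes rose. The glutamate receptor list as a whole did not move beyond the spread between libraries. Its mean log2 CPM was 6.85 ± 0.131 in WT and 6.92 ± 0.0717 in HOM (SD, n = 4, exact two-sided permutation test, p = 0.4). The same exact permutation test gave p = 0.0286 for vesicle genes, 0.0571 for GABA-A receptor genes and 0.171 for axon initial segment genes. Of 25 vesicle genes 6 fell and 1 rose (median -0.18; camera adjusted p = 6.19e-06; adjusted p = 0.253 with an estimated correlation): Snap25, a SNARE protein gene, went from 2303 ± 169 to 1829.6 ± 91.5 CPM, Cplx2 from 1473 to 1156 CPM. Cplx1 (log2 fold change -0.34), Vamp1 (-0.36), Nsf (-0.27) and Sv2b (-0.32) fell, and Syn3 (0.36) rose. Of 18 ionotropic glutamate receptor genes 3 rose, among them Gria1 (0.25) and Grik4 (0.43), and none fell (median 0.10; camera adjusted p = 0.0429; adjusted p = 0.526 with an estimated correlation). Of 16 GABA-A receptor genes 2 fell, among them Gabra5 (-0.45), and none rose (median -0.15; camera adjusted p = 0.00442; adjusted p = 0.375 with an estimated correlation). The annotation places 0.90 of the span of Gabra5 under other genes, so its value is uncertain. Of 21 genes of the axon initial segment and node of Ranvier, Cntnap1 (-0.33), Fgf13 (-0.28) and Synpo (-0.30) fell and Fgf14 (0.51) rose (median -0.16; camera adjusted p = 0.035; adjusted p = 0.416 with an estimated correlation). Among 20 neuropeptide genes Pnoc (-0.75), Cort (-0.83) and Npy (-0.55) fell and Tac2 (0.46) and Cartpt (0.60) rose; the median was 0.06, the mean close to 0 and the list did not pass (camera adjusted p = 0.986). Adjusted over the list alone, 9 vesicle, 1 glutamate receptor, 6 GABA-A receptor, 7 axon initial segment and 5 neuropeptide genes were lower, and 1, 6, 1, 3 and 3 were higher, in that order. Without WT replicate 3, HOM replicate 1 or HOM replicate 3, each left out alone, none of the vesicle, glutamate receptor, GABA-A receptor or axon initial segment genes passed. The same held for glutamate receptors without WT replicate 4, for GABA-A receptors without WT replicate 1 or 4 and for neuropeptides without HOM replicate 1 or 3, and no neuropeptide gene was higher without WT replicate 1, WT replicate 3 or HOM replicate 4. Camera adjusted p for the axon initial segment list was 0.143 without WT replicate 1, 0.0580 without WT replicate 3 and 0.112 without HOM replicate 4, and for the glutamate receptor list 0.105 without WT replicate 2, 0.211 without WT replicate 4, 0.0901 without HOM replicate 1 and 0.115 without HOM replicate 2. For glutamate receptors it was 0.140 with span, length and GC trends removed (median 0.04), and for the axon initial segment list 0.0773 with the replicate block, 0.0721 with 1 surrogate variable and 0.0534 without WT replicate 4 and HOM replicate 4. With the choroid plexus covariate no member of these 5 lists passed, at medians of -0.27 for vesicle (camera adjusted p = 1.48e-07), 0.12 for glutamate receptor (0.305), -0.14 for GABA-A receptor (0.0720), -0.09 for axon initial segment (0.0165) and -0.03 for neuropeptide genes (0.556).

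Stress and immune genes showed few calls. Of 23 protein folding genes Hsp90aa1 fell (-0.29, SE 0.08) and 22 did not pass (median -0.14; camera adjusted p = 0.0234; adjusted p = 0.526 with an estimated correlation). The camera adjusted p of protein folding genes was 0.178 without WT replicate 4 (median -0.08), 0.127 without HOM replicate 2 and 0.687 with the choroid plexus covariate (median -0.00267). None of 18 interferon and antigen presentation genes passed (camera adjusted p = 0.263). Complement gene C4b rose from 21.7 ± 5.34 to 34.7 ± 2.43 CPM and ceruloplasmin gene Cp fell (-0.60) among 11 reactive astrocyte genes (camera adjusted p = 0.88), and Axl fell (-0.23) among 16 genes of disease-associated microglia (camera adjusted p = 0.889). The 10 mitochondrially encoded genes had a median of -0.29 with none past the test one by one (camera adjusted p = 0.00442; adjusted p = 0.375 with an estimated correlation; 7 lower when adjusted over the list alone, and 7 past the test without HOM replicate 2). The mitochondrial share of counts was 4.13% ± 0.316 in WT and 3.603% ± 0.429 in HOM (SD, n = 4; exact two-sided permutation test, p = 0.0857). The 74 cytosolic ribosomal protein genes had a median of 0.19 with none past the test (camera adjusted p = 8.06e-07; adjusted p = 0.565 with an estimated correlation). That median was 0.09 without WT replicate 1, 0.11 without HOM replicate 4 and 0.08 with 1 surrogate variable, and 1 gene passed without WT replicate 2. Mean log2 CPM of the ribosomal protein genes did not separate the genotypes (exact two-sided permutation test, p = 0.257). Of 77 nuclear oxidative phosphorylation genes 1 was lower (median 0.01; camera adjusted p = 0.93). The list passed both ways elsewhere: its median was 0.10 without WT replicate 2 (0.0308), -0.04 without HOM replicate 4 (0.0495) and -0.07 with 1 surrogate variable (0.00299, with 11 genes lower). No member of the folding, reactive astrocyte, microglial or oxidative phosphorylation lists passed without WT replicate 3, HOM replicate 1 or HOM replicate 3, and no folding, microglial or oxidative phosphorylation gene without WT replicate 1, WT replicate 4 or HOM replicate 4. With p adjusted over the list alone, 1 reactive astrocyte gene was higher and 1 lower, 1 microglial gene was higher and 3 lower, and 0 passed among protein folding, interferon, ribosomal and oxidative phosphorylation genes.

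Markers of blood vessels, meninges and choroid plexus were lower in HOM on balance, although most did not pass one by one. Mean log2 CPM separated the genotypes for endothelial markers (n = 4, exact two-sided permutation test, p = 0.0286). It also did for pericyte and smooth muscle markers (exact two-sided permutation test, p = 0.0286). It did not for choroid plexus markers (exact two-sided permutation test, p = 0.0571). Nor did it for fibroblast and meninges markers (exact two-sided permutation test, p = 0.114). Choroid plexus markers stood out, with 6 of 15 lower and a median log2 fold change of -2.39 (camera adjusted p = 3.74e-10; adjusted p = 0.362 with an estimated correlation; 15 lower when adjusted over the list alone). F5 (-3.27), Aqp1 (-2.38), Kl (-2.39) and Steap1 were among them. The most abundant, the transthyretin gene Ttr, did not pass and varied widely, at 354, 314, 122 and 1517 CPM in WT replicates 1 to 4 and 202, 7.10, 19.0 and 10.8 CPM in HOM replicates 1 to 4 (edgeR adjusted p = 0.0846). The median was -1.41 without WT replicate 4, -1.26 without WT replicate 4 and HOM replicate 4 together and 0.14 with the covariate (camera adjusted p = 0.887), which is made of these markers. No choroid plexus marker passed when WT replicate 4, HOM replicate 2, HOM replicate 3 or HOM replicate 4 was left out, and 1 passed without WT replicate 1, with limma-voom and with robust quasi-likelihood. Endothelial markers Slc2a1 (-0.57), Flt1 (-0.47), Cdh5 (-0.52), Abcb1a (-0.42) and Itm2a (-0.28) fell among 12 measured (median -0.36; camera adjusted p = 7.93e-07; adjusted p = 0.253 with an estimated correlation). None passed without WT replicate 3, HOM replicate 1 or HOM replicate 3, 1 passed without WT replicate 1, without HOM replicate 4 or with the choroid plexus covariate, and 3 without WT replicate 2 or HOM replicate 2. Myh11 (-0.74) and Abcc9 (-0.53) fell among 11 pericyte and smooth muscle markers (median -0.29; camera adjusted p = 2.38e-04; adjusted p = 0.118 with an estimated correlation). Igfbp2 (-1.07) and Aldh1a2 (-0.69) fell among 9 markers of fibroblasts and meninges (median -0.54; camera adjusted p = 6.03e-04; adjusted p = 0.416 with an estimated correlation). No pericyte and smooth muscle marker passed without WT replicate 1, HOM replicate 1, HOM replicate 3 or HOM replicate 4, and 1 passed without WT replicate 3. Of the fibroblast and meninges markers none passed without HOM replicate 1 or HOM replicate 3, 1 passed without WT replicate 1, 2, 3 or 4 or HOM replicate 2, and 6 passed without HOM replicate 4, with a median of -0.82. With the choroid plexus covariate no marker of these 2 lists passed, at medians of -0.21 for pericyte and smooth muscle (camera adjusted p = 0.00220) and -0.51 for fibroblast and meninges markers (0.00777), and the endothelial median was -0.43 (9.91e-08). Of these markers 9 endothelial, 5 pericyte and smooth muscle and 4 fibroblast and meninges ones were lower when adjusted over the list alone.

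**Figure D4:**
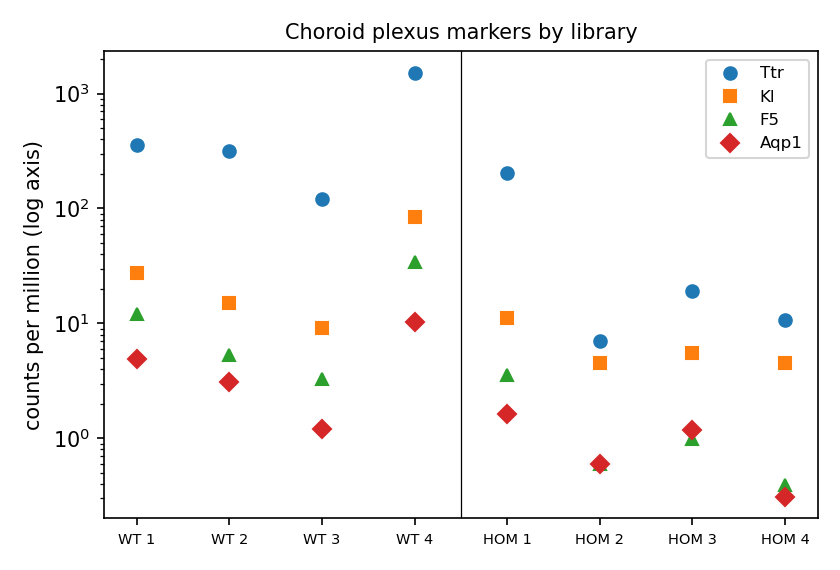
CPM on a log axis of the choroid plexus markers Ttr, Kl, F5 and Aqp1 in each of the 8 libraries. WT replicate 4 holds the highest level of each gene, 1517 CPM for Ttr, and HOM replicate 1 the highest of the HOM libraries, 202 CPM for Ttr.

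Of 15 cortical excitatory neuron markers Lamp5 (-0.84) and Neurod6 (-0.29) fell in HOM, with a list median of -0.09 (camera adjusted p = 0.0429; adjusted p = 0.526 with an estimated correlation). Of 12 inhibitory neuron markers Gad1, which encodes a GABA-synthesizing enzyme, fell from 332 ± 13.3 to 238 ± 18.7 CPM, and Npy fell (median -0.10; camera adjusted p = 0.0189; adjusted p = 0.322 with an estimated correlation). Slc1a6 (0.34) and the sparse transcript Ppp1r17 (1.86, from 0.153 to 0.551 CPM) rose among 10 cerebellar markers (median 0.44, and -0.01 with a filter of 1 CPM; camera adjusted p = 0.0308; adjusted p = 0.460 with an estimated correlation). Fibcd1 (-0.57) fell among 11 hippocampal markers (camera adjusted p = 0.0625). The exact two-sided permutation test of mean log2 CPM gave p = 0.143 for excitatory, 0.0571 for inhibitory, 0.0286 for cerebellar and 0.343 for hippocampal markers. Adjusted over the list alone, 3 excitatory, 3 inhibitory, 1 cerebellar and 1 hippocampal markers were lower and 5 cerebellar ones were higher. For excitatory markers camera adjusted p was 0.103 without WT replicate 1, 0.181 without WT replicate 2, 0.0733 without WT replicate 3, 0.0904 without HOM replicate 1, 0.0541 with the replicate block and 0.0592 with 1 surrogate variable. Their median was -0.15 without WT replicate 4 (0.00116), -0.17 without WT replicate 4 and HOM replicate 4 (7.64e-04) and -0.06 with upper-quartile scaling. The inhibitory median was -0.17 without WT replicate 1, -0.15 without HOM replicate 4, -0.06 without WT replicate 2 (0.0817), -0.06 without HOM replicate 1, -0.06 with upper-quartile scaling, -0.18 with 1 surrogate variable and -0.15 with span, length and GC trends removed. For cerebellar markers camera adjusted p was 0.0870 without WT replicate 1, 0.122 without WT replicate 2, 0.0887 without HOM replicate 1 and 0.0720 with 1 surrogate variable. The hippocampal list passed without WT replicate 2 (0.0211), WT replicate 3 (0.0173), HOM replicate 3 (0.0402) or HOM replicate 4 (0.0205), with upper-quartile scaling (0.0491), the replicate block (0.0409) and trends removed (0.0449). One by one, Lamp5 and Gad1 passed with each library left out in turn, Neurod6 when HOM replicate 2 was, and no cerebellar or hippocampal marker without WT replicate 1, WT replicate 3, HOM replicate 1 or HOM replicate 3. With the choroid plexus covariate 1 marker, Lamp5, passed, and medians were -0.26 for excitatory (camera adjusted p = 4.71e-06), -0.16 for inhibitory (0.0227), 0.79 for cerebellar (1.79e-05) and 0.08 for hippocampal markers (0.930).

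Astrocyte markers Aqp4 (-0.40) and Slco1c1 (-0.41) fell in HOM among 13 measured (median -0.13; camera adjusted p = 0.00184; adjusted p = 0.375 with an estimated correlation). None of 15 oligodendrocyte markers passed one by one (median -0.29; camera adjusted p = 1.17e-04; adjusted p = 0.420 with an estimated correlation). Their median was -0.17 without WT replicate 4 and -0.12 with the choroid plexus covariate, under which the list did not pass (camera adjusted p = 0.229), and 2 were lower without WT replicate 1. Enpp6 (-0.52) fell among 9 oligodendrocyte precursor markers (median -0.20; camera adjusted p = 0.0476; adjusted p = 0.436 with an estimated correlation). C1qa (0.44) rose among 12 microglia markers (median 0.17; camera adjusted p = 0.00231; adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone, 3 astrocyte, 7 oligodendrocyte and 2 precursor markers were lower and 1 precursor and 5 microglia markers were higher. The astrocyte median was -0.20 without WT replicate 1 and -0.09 without HOM replicate 1. For precursor markers camera adjusted p was 0.122 without WT replicate 2, 0.118 without WT replicate 4 (median -0.13), 0.147 without HOM replicate 1 and 0.0744 without WT replicate 4 and HOM replicate 4 together. One by one, no microglia marker passed without WT replicate 1, 3 or 4 or HOM replicate 1, 3 or 4, no precursor marker without WT replicate 2, 3 or 4 or HOM replicate 1, 3 or 4, and no astrocyte marker without HOM replicate 3. With the covariate no marker of these 4 lists passed, at medians of -0.20 for astrocyte (camera adjusted p = 0.00953), -0.20 for precursor (0.108) and 0.23 for microglia markers (0.00953).

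Striatal, thalamic, hypothalamic and brainstem, ependymal, blood cell and Y-linked lists did not pass, with camera adjusted p = 0.230, 0.889, 0.535, 0.889, 0.225 and 0.187 and no member past the test, one by one or adjusted over the list alone. Their medians were 0.12, -0.22, 0.23, 0.01, -0.30 and -0.36; the ependymal mean was -0.11. Some passed elsewhere: the striatal list without WT replicate 4 (0.0240) or HOM replicate 3 (0.00796), the blood cell list without HOM replicate 1 (1.13e-04, median -0.81) and the Y-linked list without HOM replicate 3 (0.0456). The thalamic median turned to 0.20 without WT replicate 4 (0.0783) and to 0.27 without WT replicate 4 and HOM replicate 4 (0.0239), and the Y-linked median to 0.08 without HOM replicate 4 (0.846). With the choroid plexus covariate the thalamic median was 0.45 (4.71e-06), the hypothalamic and brainstem one 0.44 (0.00609), the ependymal one 0.74 (7.77e-04) and the blood cell one 0.50 (0.0154). The ependymal median lay on either side of 0, from -0.13 to 0.37, with 1 library left out.

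Genes flanking the trapped locus were not shown to change more often than others. Within 5 Mb of Scn2a, 3 of 48 tested genes were lower in HOM, namely Scn1a, Gad1 and Klhl23, which was chosen after its values were seen, against 5.40% of genes elsewhere (odds ratio 1.17, 95% interval 0.232 to 3.65; Fisher's exact test, two-sided p = 0.744).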

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

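The tests of choroid plexus carry-over and of a genotype effect were chosen after the result was seen. Of 470 groups of 4 values examined, 36 had a library far from the other 3 by Dixon's criterion, which sets the gap to the nearest library against the group's range. By chance this happens in about 1 in 20 groups.

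Kcne2 was highest in WT replicate 4, at 11.005 CPM against 2.46 CPM in the nearest library (gap 0.848 of the range). Kl was highest in HOM replicate 1, at 11.2 CPM against 5.52 CPM in the nearest library (gap 0.847 of the range). Ttr was highest in WT replicate 4, at 1517 CPM against 354 CPM in the nearest library (gap 0.833 of the range). Ttr was highest in HOM replicate 1, at 202 CPM against 19.0 CPM in the nearest library (gap 0.939 of the range). Carry-over of choroid plexus tissue in dissection predicts markers that vary together between libraries of 1 genotype, and their mean pairwise correlation of deviations from group means was 0.840, so carry-over may account for the pattern. A genotype effect could not be told apart from it: the mean marker level of the libraries gave an exact permutation p = 0.0571, and the 4 libraries per genotype leave it open.

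Tsks was highest in WT replicate 2, at 2.08 CPM against 1.24 CPM in the nearest library (gap 0.922 of the range). Trpm1 was highest in HOM replicate 4, at 2.97 CPM against 2.21 CPM in the nearest library (gap 0.871 of the range). Ntsr1 was lowest in WT replicate 4, at 13.6 CPM against 15.4 CPM in the nearest library (gap 0.846 of the range). Egr1 was highest in WT replicate 3, at 433 CPM against 361 CPM in the nearest library (gap 0.876 of the range). Samd3 was lowest in HOM replicate 2, at 0.949 CPM against 1.55 CPM in the nearest library (gap 0.993 of the range). Kcnj10 was highest in WT replicate 4, at 222 CPM against 179 CPM in the nearest library (gap 0.926 of the range). Kcnk2 was highest in HOM replicate 2, at 68.1 CPM against 59.7 CPM in the nearest library (gap 0.833 of the range). Cacna1c was highest in HOM replicate 1, at 322 CPM against 245 CPM in the nearest library (gap 0.885 of the range). Fgf13 was highest in WT replicate 3, at 158 CPM against 152 CPM in the nearest library (gap 0.891 of the range). Egr3 was lowest in HOM replicate 4, at 90.4 CPM against 101 CPM in the nearest library (gap 0.852 of the range). Npy was highest in WT replicate 2, at 44.0 CPM against 31.7 CPM in the nearest library (gap 0.851 of the range). Cry1 was lowest in WT replicate 1, at 22.3 CPM against 28.1 CPM in the nearest library (gap 0.914 of the range). Hsp90aa1 was highest in HOM replicate 2, at 899 CPM against 817 CPM in the nearest library (gap 0.962 of the range). Hsph1 was lowest in WT replicate 2, at 236 CPM against 262 CPM in the nearest library (gap 0.832 of the range). C4b was highest in WT replicate 4, at 29.7 CPM against 19.9 CPM in the nearest library (gap 0.858 of the range). Hspb1 was lowest in HOM replicate 2, at 2.25 CPM against 3.503 CPM in the nearest library (gap 0.860 of the range). Lct was highest in WT replicate 4, at 6.28 CPM against 1.84 CPM in the nearest library (gap 0.855 of the range). Slc1a6 was lowest in WT replicate 1, at 12.9 CPM against 13.4 CPM in the nearest library (gap 0.830 of the range). Fat2 was highest in HOM replicate 1, at 3.93 CPM against 0.713 CPM in the nearest library (gap 0.925 of the range). Avp was highest in HOM replicate 1, at 15.3 CPM against 1.92 CPM in the nearest library (gap 0.934 of the range). Hba-a1 was highest in HOM replicate 1, at 42.0 CPM against 17.7 CPM in the nearest library (gap 0.844 of the range). Hbb-bs was highest in HOM replicate 1, at 64.7 CPM against 26.8 CPM in the nearest library (gap 0.888 of the range). Meg3 was lowest in WT replicate 4, at 2982 CPM against 3262 CPM in the nearest library (gap 0.920 of the range).

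For reactive astrocyte genes the mean log2 CPM was highest in WT replicate 4, at 3.09 against 2.86 (gap 0.853 of the range). For cortical excitatory neuron markers the mean log2 CPM was lowest in WT replicate 4, at 6.78 against 6.996 (gap 0.836 of the range). For cortical excitatory neuron markers the mean log2 CPM was lowest in HOM replicate 1, at 6.79 against 6.87 (gap 0.834 of the range). For oligodendrocyte precursor markers the mean log2 CPM was lowest in HOM replicate 1, at 4.83 against 5.05 (gap 0.837 of the range). For blood cell genes the mean log2 CPM was highest in HOM replicate 1, at 2.35 against 1.19 (gap 0.869 of the range). For Y-linked genes the mean log2 CPM was lowest in HOM replicate 4, at -3.78 against 5.15 (gap 0.963 of the range). Mitochondrial genes took 4.24% of the counts in HOM replicate 2 and 3.44% in the nearest HOM library (gap 0.866 of the range). The ribosomal RNA gene CT010467.1 took 1.70% of the counts in WT replicate 2 and 0.739% in the nearest WT library (gap 0.919 of the range). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty held 2 counts in HOM replicate 4 and 5206 in the nearest HOM library (gap 0.925 of the range).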

How the results depend on the processing

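The removal of WT replicate 4 together with HOM replicate 4, the choroid plexus covariate and the removal of span, length and GC trends were chosen after the data were seen; all other alternatives were fixed before the data were examined. The fold change of Scn2a in HOM against WT stayed lower and past the threshold under each alternative run, at log2 fold changes from -1.87 to -1.68, and from -1.84 to -1.69 with 1 library left out. The number of changed genes was 940 (429 higher and 511 lower) as reported. It was 1873 (819 higher and 1054 lower) with DESeq2, 2338 (995 higher and 1343 lower) with 1 surrogate variable and 2270 (1003 higher and 1267 lower) with span, length and GC trends removed. It was 335 (135 higher and 200 lower) without WT replicate 4 and HOM replicate 4, 38 (10 higher and 28 lower) with the choroid plexus covariate and 55 (15 higher and 40 lower) at a log2 fold change of at least 1. Whether replicate numbers pair the samples is not said in the labels. Same-numbered libraries had correlations of deviations of 0.0473, -0.196, -0.00701 and 0.0275, and differently numbered ones ran from -0.215 to 0.248. These values give no sign of pairing but cannot exclude it. A replicate block gave 364 changed genes (169 higher and 195 lower). With 1 library left out the changed genes numbered 180 to 1187, the higher ones 67 to 538 and the lower ones 89 to 649. All of these exceeded the full counts without HOM replicate 2, and without WT replicate 2 the total and the lower ones did (957 and 597) but not the higher ones (360). The lists past the threshold numbered 22, with 18 to 26 when 1 library was left out, 1 with an estimated correlation and 10 with fry. The odds ratio near Scn2a, 1.17, turned to 0.890 at 20 Mb and 0.998 with the replicate block, and was 1.14 to 2.08 with 1 library left out; the cause was not tested. Log2 fold changes of genes that turned sign, none past the threshold after the turn, were, with the choroid plexus covariate, gene Kcne2 0.37, gene Lct 0.26, gene Dsp 1.34, gene Slc17a6 0.13, gene Ramp3 0.0555, gene Glra1 0.0903, gene Kl 0.14, gene Hdc 0.00341, gene Foxj1 0.23, gene Dynlrb2 0.90, gene Hba-a2 0.44, gene Hba-a1 0.44, gene Hbb-bs 0.50, gene Hbb-bt 0.78, gene Eif2s3y 0.13, gene Scg2 0.10. Of the lists that had passed, the choroid plexus median turned with the covariate, to 0.14. Of those that had not, the thalamic and blood cell medians turned with it to 0.45 and 0.50 and passed, as did the thalamic one at 0.27 without WT replicate 4 and HOM replicate 4 and oxidative phosphorylation genes at -0.07 with 1 surrogate variable and -0.04 without HOM replicate 4. Further turns of genes were, without WT replicate 4 and HOM replicate 4, gene Dynlrb2 0.15, gene Hbb-bt 0.0452, gene Uty 0.0270, gene Kdm5d 0.16, gene Eif2s3y 0.45, gene Scg2 0.0397. Leaving out 1 library turned some of these, with ranges over the 8 removals of gene Avp -0.33 to 2.09, gene Dynlrb2 -0.81 to 0.0145, gene Uty -0.62 to 0.0529, gene Kdm5d -0.53 to 0.11, gene Eif2s3y -0.43 to 0.31, gene Scg2 -0.13 to 0.0104. The cause was not tested, except that a covariate made of choroid plexus markers removes their shared level by construction.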

Other observations

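The tests of time of day, excitatory neuron share, handling, long genes by power or nuclear RNA, and MAPK feedback genes were chosen after the results were seen, as was the comparison of long genes at an equal number of calls.

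In the imprinted domain from Dlk1 to Dio3, on chromosome 12 from 109452823 to 110281097 in GRCm38, 7 of 27 tested genes rose and none fell (edgeR, adjusted p under 0.05), with a median log2 fold change of 0.74. Besides Dio3, the long noncoding RNA genes Meg3 (0.36, from 3199 to 4096 CPM) and Mirg (0.41, from 55.2 to 73.1 CPM) and the retrotransposon-derived gene Rtl1 (0.50, from 16.7 to 23.6 CPM) rose, all chosen after their values were seen, while Dlk1 (0.47, SE 0.19) and Rian (0.09, SE 0.06) did not pass. The domain was picked because its genes were high, so these data do not test whether it moves together, and 17 of its members had means below 1 CPM.

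Feedback genes of the MAP kinase pathway, chosen after the immediate early genes were seen, were lower in part. Of 13 tested, 6 fell and none rose: the phosphatase genes Dusp4 (-1.03) and Dusp5 (-0.74), Spry4 (-0.75), Spry2 (-0.41), Spred2 (-0.33) and the transcription factor gene Etv5 (-0.41). The hypothesis that these genes move together set at least 0.5 of them past the threshold for it and at most 1 against it, so 6 of 13 decides neither.

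The 35 splits of the libraries into 4 and 4 hold 1 with as many as 940 changed genes, the genotypes, and the highest other split called 1 gene. Splits that mix the genotypes carry any genotype difference as spread within groups, which lowers their calls. A count of 1 split is the smallest that the design allows and lies below the 5% set beforehand. It argues against chance for the changed genes without excluding it. The same holds for the 429 higher and 511 lower genes, each reached in 1 split, with 1 gene as the highest other. For the number of gene lists chance cannot be excluded, since 3 splits called as many as 22 lists and the highest other called 22. Splits that mix the genotypes called between 7 and 22 of the 39 lists while calling at most 1 gene. Camera p-values with the preset correlation therefore cannot be taken at face value in these libraries.

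Among immediate early genes the median absolute log2 fold change of 0.77 was reached in 1 split, with 0.716 as the highest other. This argues against chance without excluding it, since 1 split is the smallest count possible and the margin is narrow. A lower share of excitatory neurons is argued against by the markers of these cells, whose median of -0.0896 (SD 0.256) lies nearer 0 by more than their spread; it was -0.15 without WT replicate 4, -0.17 without WT replicate 4 and HOM replicate 4 and -0.26 with the choroid plexus covariate, where the immediate early genes stood at -0.80. Time of day at dissection stays open: 4 of the 15 circadian genes passed, a share below the 0.5 set for it and a count above the 1 set against it, and Arntl (0.27, SE 0.08) and Hlf (-0.29, SE 0.09) did not pass. An earlier test on 11 of these genes is void, since it left out the 4 that fell. Handling before dissection may contribute and stays open, with 2 of 6 slower genes lower and a median of -0.30, and reduced neuronal activity in HOM was not tested apart from these.

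The longest genes were more frequent among higher than lower genes: the longest eighth of protein-coding genes held 92 higher and 60 lower ones. The second longest eighth held 50 higher and 88 lower ones, so the excess did not extend to all long genes. Greater power in long genes is argued against by Fisher's exact test of the shares in the longest eighth (two-sided p = 2.72e-07, odds ratio 2.57, 95% interval 1.77 to 3.76), since power favours neither direction. After a smooth trend with span, exonic length and GC content was removed from each library the odds ratio was 0.998 (0.792 to 1.255). It was 0.911 (0.641 to 1.29) at an equal number of calls. The removal flattens any smooth dependence on span by construction, whatever its source. These values show only that the excess goes with such a trend, and not what caused it. The bound first set against the trend, on higher genes still called, was met by 84 of the 92. It decides nothing, because 97.2% of all calls were kept. More unspliced or nuclear RNA in HOM stays open: the median of all genes in that eighth was 0.0146, below the 0.0324 of the shortest eighth but above the other 6, which ran from 0.00646 in the second shortest to -0.0496 in the second longest, and medians were 0.11 for lincRNA and 0.12 for antisense genes against -0.01 for protein-coding ones, and the lincRNA share was 1.31% in WT and 1.57% in HOM (exact permutation p = 0.0286).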
